A study of Homo sapiens with 56 samples.

How the data were processed

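Long RNA (the fraction left after small RNA was removed) from biopsies of the sigmoid colon was hybridised to an array carrying probes for non-coding transcripts, and 56 samples were analysed here: 14 normal controls (CTR), 14 samples of inactive ulcerative colitis (iUC), 14 of active ulcerative colitis (aUC), 5 of active Crohn's disease of the colon (aCD), 4 of infectious colitis (INF) and 5 of irritable bowel syndrome (IBS). Groups were taken from the group label of each sample. Each sample was treated as 1 replicate, and replicate numbers follow the order of deposition and pair nothing. The labels do not state whether samples came from separate people, so p-values measure the spread between these samples.

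The authors deposited 1 table of processed values, with 39185 probe rows and a column per sample. The range of the values was that of log2 scanner brightness, and the deposited values were used as log2 values. The log base, scale, centring and background correction are not given in the sources used here, so every log2 difference rests on this reading. The submitters' processing notes name limma and give no version. The normalization, the dye and the scanner settings are not given in the sources used here. Sample medians differed slightly, so the columns had not been forced to one distribution, and low values stepped between repeated levels. No value for local background or detection was used here, so a probe at the low end could not be called detected or undetected, and a fold against such a probe understates the change if the true level lies below the floor. The direction of the values was taken as higher meaning more RNA.

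The deposited rows carry probe identifiers only. None of the 39185 identifiers matched the gene table given for the human genome (0 matches), so probes are named by identifier, at most 2 higher and 2 lower per comparison, and no genome position is given. The files do not pair probe identifiers with gene names. The 29 gene lists (400 genes and transcripts) fixed before the data were examined could not be applied for this reason, and BC012900, the long non-coding RNA of the series title, could not be assigned to a probe and is not reported here. The rule for named genes, fixed before the data were examined, also covered gene lists and non-coding gene names. Without names it took the 2 probes with the largest rise and the 2 with the largest fall among those that passed the test, or fewer where fewer passed. The 27 probes whose values split into separated clusters regardless of group, or followed such probes, were not considered for naming.

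Sample titles carry an array code shared by pairs of samples (25 arrays with 2 samples, 6 with 1) and a suffix, 1 or 2, whose meaning is not given. All 14 controls carried suffix 1, against 8 of 14 iUC, 5 of 14 aUC and 1 each of the aCD, INF and IBS samples. The main model, fixed at the same time, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 56 samples as deposited, with the 6 groups and the suffix as fixed terms and the array code as a random block (duplicateCorrelation, estimated correlation 0.134). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 39185 rows of each of 8 comparisons, and a probe was called changed at an adjusted p under 0.05. No row was filtered. The suffix term itself called 0 probes by limma at the same threshold. The median centred correlation of samples sharing an array was 0.0711, against -0.0236 for other pairs, and was positive on 18 of the 25 shared arrays. No columns were identical, and the highest correlation between any pair of samples over all probes was 0.969.

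The model was tested on simulated data with the real means, spreads and layout and 200 changed probes among 39185. For aUC against CTR it recovered 30% of changes of 1 on the log2 scale and 96% of changes of 2. For aCD against CTR it recovered 8% and 78%, for INF against CTR 10% and 58%, and for IBS against CTR 4% and 70%. The number of arrays limits the precision, most of all for the 3 small groups.

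After the data were seen, array codes were sorted into 6 runs of nearby numbers, called array sets A to F, and the number of distinct values in a sample was used as a proxy for its brightness, which was not measured. Alternatives planned beforehand covered the suffix term, the array block, normalization, a filter on dim rows, sample weights, the prior, the threshold, the samples in the fit and leaving out each aCD, INF and IBS sample. Those added later covered the array sets, brightness, aUC replicate 10 and iUC replicate 8. Exact permutation tests were run in Python 3.11.15 with scipy 1.17.1.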

Results

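Transcript levels in sigmoid colon biopsies were measured on arrays in 14 normal controls (CTR) and in patients with inactive ulcerative colitis (iUC, n = 14), active ulcerative colitis (aUC, n = 14), active Crohn's disease of the colon (aCD, n = 5), infectious colitis (INF, n = 4) and irritable bowel syndrome (IBS, n = 5). Ulcerative colitis is a chronic inflammation of the colonic mucosa that alternates between active and quiet phases, and the other patient groups served as disease controls. Of the 4 INF samples, 3 carried the activity label normal and 1 the label active. Values are the authors' processed log2 values for 39185 probes, which are given by identifier because they could not be matched to genes. Group means are those of the deposited values. Log2 differences of named probes come from the fit with the suffix term, so they need not equal the difference of the printed means. Sample medians lay between 2.49 and 3.12. The number of distinct values in a sample, an unchecked proxy for its brightness, ran from 1587 to 5078 in CTR, 2166 to 5134 in iUC, 1832 to 5004 in aUC, 2133 to 4836 in aCD, 1966 to 4604 in INF and 3221 to 9029 in IBS. It did not follow the deposited scale: IBS replicate 2, with 9029, had a highest value of 12.6, and CTR replicate 11, with 1909, one of 17.1. aUC replicate 10 stood apart from the other samples, with a limma sample quality weight of 0.201, the lowest of the 56.

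Active ulcerative colitis was compared with normal mucosa to find transcripts that differ in active disease. In aUC, 1388 probes rose and 1099 fell against CTR, together 6.35% of the array, and 2005 of these 2487 probes changed at least 2-fold. The share of higher calls was 55.8%, and after quantile normalization, with 1417 probes higher and 1595 lower, it was 47.0%. Probe IVGNh10763 showed the largest rise, from 4.78 ± 1.54 (SD, n = 14) in CTR to 11.4 ± 1.76 (SD, n = 14) in aUC, a log2 difference of 6.32 with a standard error of 0.75 (limma adjusted p = 2.54e-08), and all 14 aUC samples exceeded every control. Probe IVGNh03867 rose by 5.52 ± 0.57 (SE; limma adjusted p = 5.15e-10), from 3.27 ± 0.82 in CTR to 8.78 ± 1.62 in aUC, again with no overlap. Its control level lay close to the sample medians. Probe IVGNh00267 fell by 5.996 (SE 0.90, limma adjusted p = 3.19e-06), from 9.34 ± 1.70 in CTR to 3.37 ± 2.27 in aUC, and 11 of 14 aUC samples lay below every control. Its aUC values reached down to 0.449 in replicate 11, at the low end of the array. IVGNh33490, a bright probe in controls at 13.5 ± 1.08, dropped to 8.07 ± 3.17 in aUC, a log2 difference of -5.82 (SE 0.93, limma adjusted p = 1.19e-05), with 12 of 14 aUC samples below every control.

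In the other patient groups none of these 4 probes passed the limma test against CTR, with adjusted p-values of 0.265 or more. IVGNh10763 averaged 9.01 ± 3.04 (SD, n = 4) in INF, 7.80 ± 3.19 (SD, n = 5) in aCD, 5.07 ± 1.99 (SD, n = 14) in iUC and 4.59 ± 1.90 (SD, n = 5) in IBS. IVGNh03867 averaged 6.10 ± 2.41 in INF, 5.84 ± 2.45 in aCD, 3.28 ± 1.33 in iUC and 3.06 ± 1.04 in IBS. IVGNh00267 averaged 8.48 ± 1.92 in INF, 6.62 ± 3.47 in aCD, 7.97 ± 3.06 in iUC and 9.80 ± 1.47 in IBS. IVGNh33490 averaged 10.3 ± 2.18 in INF, 11.7 ± 2.995 in aCD, 12.3 ± 3.17 in iUC and 13.4 ± 1.45 in IBS.

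Differences of the called probes were taken within each array set that held both groups, which is no independent test, since the probes were called on the same samples. In set C, with 6 aUC and 5 CTR samples, the median log2 difference was 1.45 over the probes called higher and -1.19 over those called lower, against 1.26 and -1.24 in the pooled fit. Sets A, B, E and F, with 1 or 2 aUC samples each, gave medians between 0.94 and 1.12 for the higher probes and between -1.15 and -0.68 for the lower ones. The share of called probes with the pooled direction was 83.8% in set A, 98.3% in set B, 99.7% in set C, 86.1% in set E and 94.9% in set F. Fits within single sets called 978 probes in set C, 3 in set F and 0 by limma in set B, where 2723 passed an unadjusted p of 0.05. With array set as a term the count was 2226, and without aUC replicate 10 it was 2307, with 1518 probes higher and 789 lower. A fit with the array code as a fixed block, which leaves few degrees of freedom, called 155 probes. A fit of these groups alone, whose differences rest on the 5 aUC samples of suffix 1, called 1199. In the former IVGNh33490 was not called (difference -5.29, limma adjusted p = 0.101), while the other 3 named probes were.

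**Figure D1:**
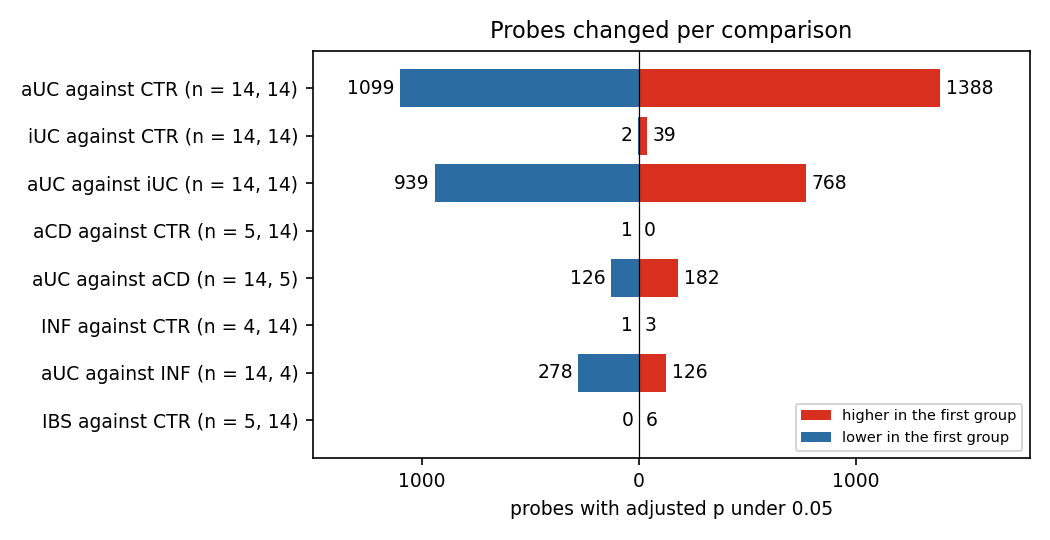
Number of probes with a limma adjusted p under 0.05 in each of the 8 comparisons (horizontal axis, probes). Bars to the right count probes higher in the group named first and bars to the left probes lower in it; aUC against CTR (1388 and 1099) and aUC against iUC (939 lower, 768 higher) hold the most.

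Active disease was next set against inactive disease within ulcerative colitis. Here 768 probes rose and 939 fell in aUC, and the named probes were those of the comparison with controls. IVGNh10763 was higher by 6.21 ± 0.67 (SE; limma adjusted p = 2.31e-09) and IVGNh03867 by 5.50 ± 0.51 (SE; limma adjusted p = 6.44e-12), and 12 and 13 of the 14 aUC samples, respectively, exceeded every iUC sample. IVGNh00267 fell by 4.51 (SE 0.80, limma adjusted p = 0.000117) and IVGNh33490 fell by 4.40 (SE 0.83, limma adjusted p = 0.000305). No aUC sample lay below every iUC sample for either probe, because iUC replicate 8 was at 0.419 for IVGNh00267 and 2.22 for IVGNh33490, whereas the other iUC samples were at 4.84 or more and 10.2 or more. Over the probes called higher, the median difference lay between 0.998 and 1.30 in the 5 array sets with both groups, and over those called lower between -1.41 and -0.44. Fits within single sets called 110 probes in set C, 5 in set F and 0 by limma in set B, where 2411 passed an unadjusted p of 0.05. Samples of suffix 1 gave 533 calls. With the array code as a fixed block limma called 0 probes, with 3435 at an unadjusted p under 0.05 and adjusted p-values of 0.0642 to 0.586 for the 4 named probes. Their differences in that fit were 4.45 for IVGNh10763, 4.39 for IVGNh03867, -2.66 for IVGNh00267 and -3.97 for IVGNh33490. Centring each sample on its median gave 1529 calls, of which 33.4% were higher in aUC, against 45.0% as deposited. The balance turned in samples of suffix 1 (281 higher, 252 lower), without aUC replicate 10 (746 and 637), without array set D (628 and 552) and with sample quality weights (1081 and 964).

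The comparisons of aUC with CTR and with iUC shared 581 probes called higher and 623 called lower, with none called in opposite directions. Independent lists of these lengths would share 27.2 and 26.3, a value that leaves out the shared aUC samples. Log2 differences of the 2 comparisons correlated at r = 0.764 across probes, which are not independent replicates, against 0.485 from the shared aUC samples alone in simulation, and their covariance was 0.185 against 0.045. With different aUC samples in each comparison, r was 0.417, and 211 probes were called higher and 207 lower in both. Here and in the later splits both fits still shared the suffix estimate, and no simulation was run for split samples. Simulated values, here and below, come from a single draw with noise independent between probes. They give no spread for r or the covariance, and real probes that vary together could depart further from them.

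Inactive ulcerative colitis differed from normal mucosa at 41 probes, 39 higher and 2 lower. IVGNh04137 rose from 7.90 ± 1.52 (SD, n = 14) in CTR to 11.4 ± 1.36 (SD, n = 14) in iUC, a log2 difference of 3.49 (SE 0.50, limma adjusted p = 5.11e-05), and 10 of 14 iUC samples exceeded every control. IVGNh13920 rose from 10.8 ± 1.47 to 14.1 ± 1.27, by 3.39 (SE 0.50, limma adjusted p = 5.11e-05), with 12 of 14 iUC samples above every control. The 39 higher probes varied together, with a median correlation of 0.418 within groups, so they are not separate findings. IVGNh39118 fell by 1.85 (SE 0.41, limma adjusted p = 0.0389) and IVGNh24916 fell by 1.19 (SE 0.27, limma adjusted p = 0.0409), with 6 and 7 of the 14 iUC samples below every control. The latter averaged 2.17 ± 0.74 in CTR and 1.02 ± 0.63 in iUC, at the low end of the array. Averaged over the 39 higher probes, the level was 4.72 ± 0.93 (SD, n = 14) in CTR, 6.45 ± 0.53 in iUC and 6.09 ± 0.26 in aUC. It was 4.52 ± 0.41 (SD, n = 5) in aCD, 4.70 ± 0.63 (SD, n = 4) in INF and 4.55 ± 0.23 (SD, n = 5) in IBS. Of the 39, 27 were also called higher in aUC against CTR, where independent lists would share 1.38. These comparisons use the same controls: across probes, which are not independent replicates, r was 0.548 against 0.586 in simulation, and the covariance 0.103 against 0.058. With the controls divided between the comparisons, r was 0.285. Of the 8 probes then called in iUC against CTR, 5 were called higher in both. As all controls carry suffix 1, the suffix estimate shared by the fits can alone raise r above 0.

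The iUC difference varied with the array set. In sets B, C and E together, the mean over the 39 probes was 4.20 ± 0.43 (SD, n = 10) in CTR and 6.46 ± 0.61 (SD, n = 10) in iUC, whereas in sets A and F it was 5.997 ± 0.36 (SD, n = 4) in CTR and 6.42 ± 0.34 (SD, n = 4) in iUC. The median log2 difference over the 39 probes was 1.80 in set B, 2.25 in set C, 2.28 in set E and 0.73 in set F, and -0.10 in set A, which held 1 iUC sample. Fits within single sets called 22 probes in set C and 0 by limma in sets B and F, where 3950 and 2466 passed an unadjusted p of 0.05. The count of 41 became 68 with array set as a term, 113 without the suffix term, 11 with brightness as an added term and 9 after quantile normalization. It was 6 in samples of suffix 1 and 6 in a fit of these groups alone, which rests mainly on the same 8 iUC samples. IVGNh04137 and IVGNh13920 stayed called in these fits of several sets, but not within set B or F or with the array code as a fixed block, where limma called 0 probes and 1519 passed an unadjusted p of 0.05. Their differences were 3.50 and 3.46 within set B, 3.09 and 3.64 with the fixed block, and 0.96 and 0.93 within set F. IVGNh39118 and IVGNh24916 kept their direction but each lost the limma call in 10 alternatives, among them suffix 1 samples (adjusted p = 0.739 and 0.785), the fit of these groups alone (0.38 and 0.439) and brightness as a term (0.064 and 0.0885).

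Crohn's colitis was examined against normal mucosa and against active ulcerative colitis. Against CTR, 1 probe was called in aCD: IVGNh33500 fell by 3.03 in the fit with the suffix term (SE 0.57, limma adjusted p = 0.0445), with 4 of 5 aCD samples below every control. Its deposited means were 5.39 ± 0.92 (SD, n = 14) in CTR and 2.63 ± 1.85 (SD, n = 5) in aCD. The 4 low aCD values, 1.24 to 2.48, lay below every sample median, at the low end of the array. The probe was also called lower in aUC against CTR (difference -2.025, limma adjusted p = 0.0004), but not called between aUC and aCD (adjusted p = 0.438). It averaged 3.59 ± 0.77 in aUC, 3.08 ± 0.79 in INF, 4.57 ± 1.06 in iUC and 5.29 ± 1.21 in IBS. At an unadjusted p under 0.05, 2171 probes differed, where chance alone gives 1959. Without aCD replicate 1, 3, 4 or 5 limma called 0 probes, with 2303, 2087, 2210 and 1944 at an unadjusted p under 0.05, and without replicate 2 it called 3. Array sets held at most 1 aCD sample each, too few for values within sets.

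Between aUC and aCD, 182 probes were higher and 126 lower in aUC. IVGNh13920, also higher in iUC than in CTR, averaged 13.2 ± 1.05 (SD, n = 14) in aUC and 9.17 ± 0.22 (SD, n = 5) in aCD, a log2 difference of 4.05 (SE 0.64, limma adjusted p = 0.000994), with all 14 aUC samples above every aCD sample. IVGNh24666 was higher in aUC by 3.77 (SE 0.87, limma adjusted p = 0.0193), at 4.99 ± 2.93 against 1.47 ± 1.19, the latter at the low end of the array. IVGNh11937 was lower in aUC by 3.13 on the log2 scale (difference -3.13, SE 0.55, limma adjusted p = 0.00149), at 2.85 ± 1.45 against 6.04 ± 0.89, and IVGNh14269 differed by -2.91 (SE 0.69, limma adjusted p = 0.0253), with 12 and 9 of the 14 aUC samples below every aCD sample. Of the 308 probes, 124 called higher and 89 called lower were also called so in aUC against CTR, where 6.45 and 3.53 would be shared by independent lists. Across probes r was 0.599 against 0.218 in simulation, and the covariance 0.163 against 0.028. With the aUC samples divided between the comparisons, r was 0.384 and 27 and 32 probes were shared. With the array code as a fixed block limma called 0 probes, with 1653 at an unadjusted p under 0.05 and an adjusted p of 0.99 for each of the 4 named probes, at differences of 4.35 for IVGNh13920, 3.54 for IVGNh24666, -2.96 for IVGNh11937 and -1.96 for IVGNh14269. The fit of these groups alone called 28. The limma call of IVGNh24666 was lost without aCD replicate 1, 2, 3 or 5 (adjusted p = 0.0717, 0.057, 0.097 and 0.0626) and that of IVGNh14269 without replicate 1, 2 or 3 (0.133, 0.144 and 0.063). Both were also lost in the fit of these groups alone and with the robust prior. The count depended on single aCD samples, at 74 without replicate 1, 20 without replicate 2 and 98 without replicate 3. After median centring it was 181, of which 41.4% were higher in aUC, against 59.1% as deposited. The balance also turned without replicate 3 (36 higher, 62 lower).

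Infectious colitis differed from CTR at 4 probes. IVGNh28092 rose by 2.81 (SE 0.55, limma adjusted p = 0.0341), from 3.92 ± 0.39 (SD, n = 14) to 6.59 ± 0.95 (SD, n = 4), and IVGNh21437 rose by 2.59 (SE 0.51, limma adjusted p = 0.0351), from 3.67 ± 0.67 to 6.39 ± 1.24. For both, all 4 INF samples exceeded every control, and the aUC means were 6.45 ± 1.35 and 5.91 ± 0.95. IVGNh34272 fell by 3.94 in the fit with the suffix term (SE 0.76, limma adjusted p = 0.0341), with 2 of 4 INF samples below every control. Its deposited means were 8.40 ± 0.98 in CTR and 5.45 ± 1.83 in INF. The difference was -2.81 without the suffix term (limma adjusted p = 0.049) and -2.96 with group alone, where the call was lost (0.0536). The limma count was 344 without INF replicate 3, 1 without replicate 4, and 0 without replicate 1 or 2, where 1973 and 2065 probes passed an unadjusted p of 0.05. It was 1785 with sample quality weights, 277 without the suffix term and 50 with array set as a term, but 0 after quantile normalization, with brightness as a term and with the array code as a fixed block (2916, 2541 and 1799 at an unadjusted p under 0.05). A fit of these groups alone rests on the 1 INF sample of suffix 1, since all controls carry suffix 1. The differences of IVGNh28092, IVGNh21437 and IVGNh34272 were 2.44, 2.50 and -1.685 there.

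Between aUC and INF, 126 probes were higher and 278 lower in aUC. IVGNh18466 averaged 6.44 ± 2.54 (SD, n = 14) in aUC and 1.61 ± 0.17 (SD, n = 4) in INF, a difference of 5.003 (SE 0.96, limma adjusted p = 0.00486), and IVGNh33986 averaged 6.14 ± 2.43 and 1.58 ± 0.27, a difference of 4.71 (SE 0.93, limma adjusted p = 0.00702). For both, all 14 aUC samples exceeded every INF sample, but the INF means lay at the low end of the array. The aUC values of IVGNh18466 ran from 2.66 in replicate 1 to 9.75 in replicate 3. The means of the 2 probes were 5.49 ± 2.24 and 5.31 ± 1.94 in iUC and 3.12 ± 1.08 and 2.21 ± 1.34 in CTR. IVGNh33379 was lower in aUC, at 9.68 ± 1.71 against 13.7 ± 1.10 (difference -4.02, SE 0.69, limma adjusted p = 0.00204), and IVGNh00267 differed by -5.01 (SE 1.21, limma adjusted p = 0.0255), with 13 and 12 of the 14 aUC samples below every INF sample. The limma call of IVGNh00267 was lost without INF replicate 2 or 4 (adjusted p = 0.12 and 0.197) and with the robust prior (0.0595), and that of IVGNh33986 without INF replicate 1 (0.0504). With the array code as a fixed block limma called 0 probes, with 2332 at an unadjusted p under 0.05, and the difference of IVGNh00267 was -0.79 (adjusted p = 0.979). No array held both aUC and INF, so this fit compared them only through other groups. With aUC against CTR, 83 probes called higher and 135 called lower were shared, against 4.46 and 7.80 for independent lists. Across probes r was 0.541 against 0.224 in simulation and the covariance 0.17 against 0.032, and with the aUC samples divided r was 0.31 and 25 and 50 probes were shared. The share of calls higher in aUC was 31.2% as deposited, 13.97% after median centring and 51.5% after quantile normalization. It was 54.2% without INF replicate 2, 16.4% without replicate 3 and 65.96% without replicate 4. The count of 404 was 58 without INF replicate 1, 24 without replicate 2, 1839 without replicate 3, 47 without replicate 4, 1122 with array set as a term and 4846 with sample quality weights.

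In irritable bowel syndrome, 6 probes were higher than in CTR and 0 were lower. In the fit with the suffix term IVGNh18784 rose by 3.26 (SE 0.67, limma adjusted p = 0.0472) and IVGNh38404 by 3.01 (SE 0.59, limma adjusted p = 0.0373). Their deposited means were 5.59 ± 0.58 and 6.38 ± 0.66 in CTR (SD, n = 14) and 8.51 ± 2.11 and 8.98 ± 2.08 in IBS (SD, n = 5). Without the suffix term the differences were 2.65 and 2.40 and neither was called (limma adjusted p = 0.166 and 0.153). With group alone they were 2.925 and 2.60 and both were called (0.0456 each). For each probe, 4 of 5 IBS samples exceeded every control. These 4 samples lay in array set D, which held no control, together with 2 aUC and 1 aCD samples. Averaged over the 6 probes, the 7 samples of set D ranged from 7.66 to 9.99 and the 49 others from 4.58 to 6.55. With array set as an added term limma called 0 probes and 1181 passed an unadjusted p of 0.05, against 1815 without that term and 1959 by chance. Without IBS replicate 1, 2, 3 or 5 limma called 0 probes, with 1576, 1401, 1905 and 1677 at an unadjusted p under 0.05, and without replicate 4 it called 55.

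**Figure D2:**
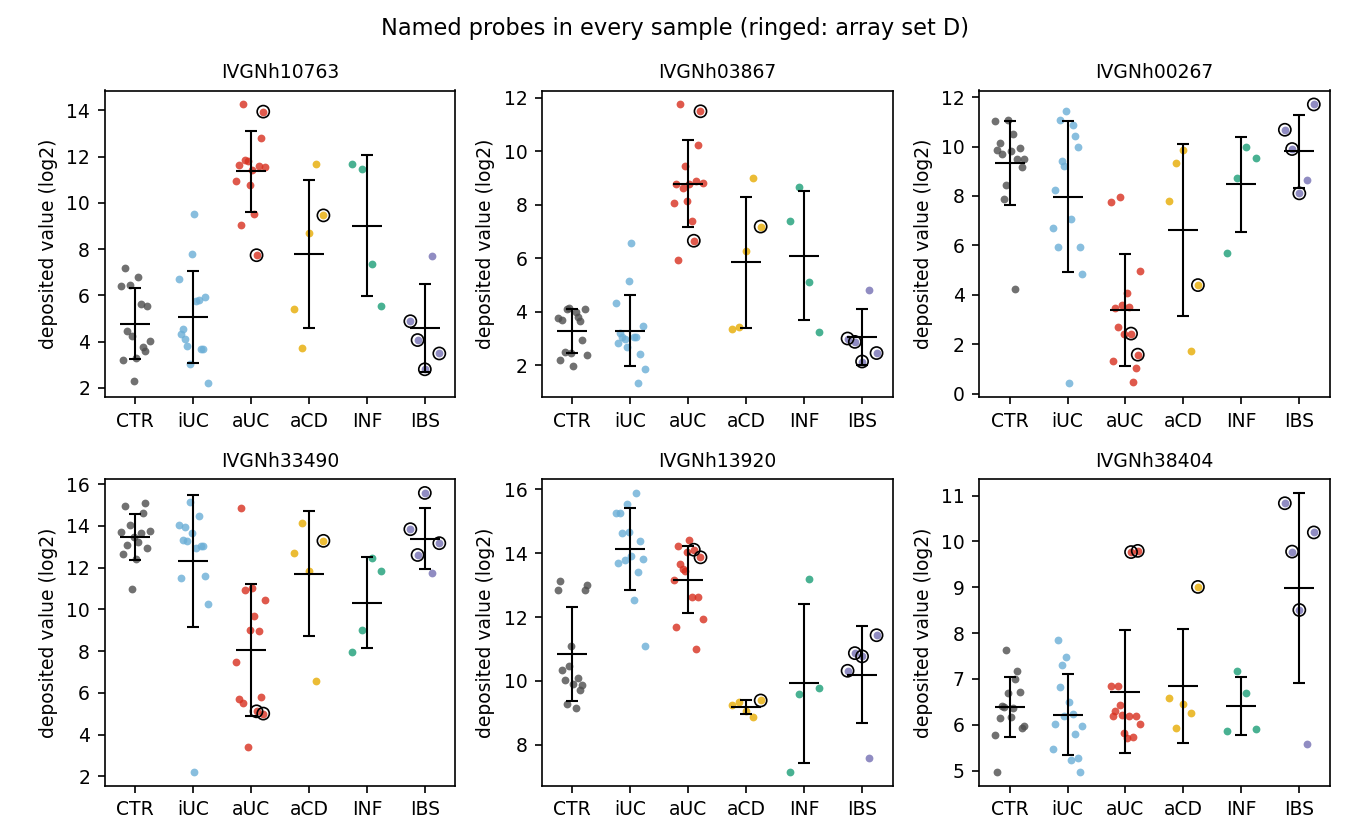
Deposited log2 values (vertical axes) of 6 named probes in all 56 samples by group; points are samples, horizontal marks and bars are the mean ± SD, and ringed points lie in array set D. IVGNh10763 and IVGNh03867 were higher in aUC than in every control, IVGNh00267 and IVGNh33490 lower on average, IVGNh13920 was high in iUC and aUC, and IVGNh38404 was high in the set D samples of every group that had them.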

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

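The fits with brightness or array set as a term and without aUC replicate 10 were added after the data were seen, and the tests of aUC replicate 10 and the suffix for aUC, of array set for iUC, of set D for IBS and of sets A and F were chosen after their results were seen, although the suffix 1 fit itself was planned.

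The 2487 probes called in aUC against CTR were set against technical explanations. Of 100 splits of these samples 1, the real one, called as many (highest other 860), which argues against chance. A smaller share cannot come from 100 splits, and it is not adjusted over the 8 comparisons. The median ratio of the log2 difference to its original value over the called probes was 0.972 with array set as a term, where 1992 stayed called. This argues against array set as the cause of the shift. Without aUC replicate 10 the ratio was 0.965, which is no test of that sample, since a probe called over 14 samples can hardly rest on 1. Without it 1903 of the 2487 stayed called, so most calls did not need this sample. The median ratio was 0.994 with the brightness proxy as a term, which was not checked against brightness itself. In suffix 1 samples it was 1.08, which cannot test the suffix, since the original fit already held that term. Suffix 1 samples alone, where the suffix cannot differ, called 1350 probes. Differences in the cell types of inflamed mucosa were not tested, since the probes could not be tied to genes. The shift of active against inactive disease was also present in aUC samples not used to choose its probes. The score difference from CTR was 3.52 with probes chosen on odd-numbered samples and 2.98 with even-numbered ones. That the shift belongs to active disease remains a hypothesis.

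The 6 probes higher in IBS follow array set D. The 3 samples of other diseases in that set lay above the remaining samples of their own groups by a median of 2.67 on the log2 scale, nearly the IBS difference of 2.83, and did so in all 18 probe-by-sample values. The 1 IBS sample outside the set differed from the controls of its own array set by a median of -0.086. Array processing is therefore a candidate explanation for these calls. An IBS effect beside it cannot be told apart, because 4 of 5 IBS samples and no control were in the set. At least as many calls as the real 6 came from 2 of 100 splits, a share not adjusted over the 8 comparisons, and another split called 9, so chance is not firmly excluded.

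The 39 probes higher in iUC than CTR differed between controls of array sets A and F and the other controls by 1.79 (4 against 10 samples, 4 of 4 above all others, exact two-sided permutation p = 0.002, adjusted p = 0.00599 over 3 groups). These sets were picked after the differences within sets were seen, on probes called against the same controls, so this p is no independent test. A set-wide processing shift should move iUC and aUC samples of the same sets too. The larger of their shifts was 0.203, in aUC (exact p = 0.291, adjusted p = 0.436), which argues against it for aUC, on 3 samples of sets A and F against 9. The iUC shift was -0.035 (exact p = 0.753, adjusted p = 0.753). It is no independent test, since calling the probes on these iUC samples favours a small spread among them. The median ratio of the log2 differences over all 41 called probes was 1.005 with array set. It was 0.948 with the unchecked brightness proxy, which left 11 calls. In suffix 1 samples it was 0.966, which cannot test the suffix, already a term of the original fit, and 6 probes were called. Of 100 splits 1, the real one, called 41 probes (highest other 2), which argues against chance. A smaller share cannot come from 100 splits, and it is not adjusted over the 8 comparisons. Differences between the control donors of these sets, or in handling of the controls alone, may be involved (shift 0.203 in aUC and -0.035 in iUC) and were not tested.

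The effects of aUC and aCD against the same controls differed at 308 probes, and those of aUC and INF at 404, each by a limma test of the difference. As many were called by 1 of 100 splits for aCD (highest other 164) and by 4 of 100 for INF, where another split called 3020, which points to a structure of the samples. Neither share is adjusted over the 8 comparisons, and the aCD count fell to 20 without aCD replicate 2, so chance is not firmly excluded for either.

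Samples far from their group were sought in 22 sets of values, of which chance gives about 1 in 20 (1.1 here), and 3 were found. For IVGNh18784, IBS replicate 4, the sample outside set D, was at 4.83 against 8.75 or more in the others (gap over range 0.759). For IVGNh33500, aCD replicate 2 was at 5.75 against 1.24 to 2.48 in the others (0.725). For the activity score described under the other observations, iUC replicate 8 stood at 3.79 against -0.576 to 0.417 in the other held-out iUC samples (0.773).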

How the results depend on the processing

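Alternatives on array sets, brightness, aUC replicate 10 and iUC replicate 8 were chosen after seeing the data, and the others before. An adjusted p under 0.01 left 1278 probes for aUC against CTR, 7 for iUC against CTR, 824 for aUC against iUC, 0 for aCD against CTR, 34 for aUC against aCD, 0 for INF against CTR, 51 for aUC against INF and 0 for IBS against CTR. Without the suffix term, iUC against CTR gave 113, aCD 3, INF 277, IBS 0 and aUC against INF 712. Without the array block, aCD gave 2 and IBS 24, and with group alone iUC gave 93, aCD 2, INF 132 and IBS 12. Suffix 1 samples gave 1350 for aUC against CTR, 6 for iUC against CTR and 533 for aUC against iUC. With the array code as a fixed block aUC against CTR gave 155 and each of the other comparisons 0, in a fit with far fewer residual degrees of freedom. Quantile normalization gave 9 for iUC and 0 each for aCD, INF and IBS against CTR. Median centring gave 0 for aCD, 21 for IBS and 181 for aUC against aCD. Leaving out the dim rows gave 4 for aCD, 485 for aUC against aCD and 1094 for aUC against INF. Fits of the compared groups alone gave 1199 for aUC and 6 for iUC against CTR, 28 for aUC against aCD and 86 for aUC against INF. For aCD, INF and IBS against CTR such a fit rests on the 1 sample of suffix 1, so its count is left out. Sample weights gave 94 for iUC, 5 for aCD, 1785 for INF, 44 for IBS and 4846 for aUC against INF, and the trended robust prior 0 for aCD and 2 for IBS. INF samples labelled normal alone gave 1 against CTR and 47 against aUC. Leaving out 1 sample at a time gave 0 to 3 for aCD against CTR, 20 to 373 for aUC against aCD, 0 to 344 for INF against CTR, 24 to 1839 for aUC against INF and 0 to 55 for IBS against CTR. Array set as a term gave 68 for iUC, 50 for INF, 0 for IBS and 1122 for aUC against INF. Without set D, aCD gave 0, INF 1 and IBS 0. Brightness as a term gave 11 for iUC and 0 each for aCD, INF and IBS. Within set B each of the 3 ulcerative colitis comparisons gave 0, within set C 978 (aUC against CTR), 22 (iUC against CTR) and 110 (aUC against iUC), and within set F 3, 0 and 5. The limma counts of 0 came with 923 to 3950 probes at an unadjusted p under 0.05. All other alternatives, those fits on 1 sample aside, moved a count by at most 1.5 times. Over the named probes, 292 planned and 95 added repeats kept direction and call, 99 and 40 kept direction only, and 1 and 3 reversed: IVGNh18784 in IBS to -0.935 with the fixed array block, -0.112 with array set as a term and -0.602 without set D, and IVGNh38404 to -0.430 without set D. Apart from array set, for which the values of set D in other groups bear on the cause in IBS, and the stricter threshold, which lowers counts by construction, the cause was not tested. Averaging rows of a gene, the gene list tests and BC012900 were not run, for lack of gene names. What signal over background limits could not be assessed without background values. Replicate numbers only follow deposition order and pair nothing, so only samples sharing an array could be paired. No array held INF together with CTR or aUC, or aCD or IBS together with CTR. Where aUC or iUC shared an array with CTR, the control carried suffix 1 and the other sample suffix 2. Where aUC shared one with iUC, aUC carried suffix 1. The fit with the array code as a fixed block is therefore no clean paired test, and its lost calls do not show that pairing removes a difference.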

Other observations

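The score tests were set out before the scores were seen, and only the fits without iUC replicate 8 were chosen after.

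Active Crohn's disease and infectious colitis each gave few calls against controls, and it was asked whether they share the shift of active against inactive ulcerative colitis at a lower level. The 200 probes highest and 200 lowest by moderated statistic were chosen on the odd-numbered aUC and iUC samples, and the score, the mean of the former minus the mean of the latter relative to CTR, was taken in samples not used for the choice. It was 3.52 ± 0.79 (SD, n = 7) in aUC, 1.11 ± 1.01 (SD, n = 5) in aCD, 1.04 ± 0.94 (SD, n = 4) in INF, -0.226 ± 0.64 (SD, n = 5) in IBS and 0.550 ± 1.47 (SD, n = 7) in iUC, with a control SD of 0.44 (n = 14). By exact two-sided permutation tests, adjusted over 6 comparisons, aCD exceeded CTR (exact p = 0.00912, adjusted p = 0.0182; 2 of 5 above every control), as did INF (exact p = 0.0177, adjusted p = 0.0265; 2 of 4), aUC exceeded CTR (exact p = 1.72e-05, adjusted p = 0.000103; 7 of 7), and aUC exceeded aCD by 2.41 (exact p = 0.00505, adjusted p = 0.0152; 6 of 7 above every aCD sample). IBS (exact p = 0.386, adjusted p = 0.386) stayed within 1 control SD. For iUC (exact p = 0.318, adjusted p = 0.381) no call could be made, and 1 of 7 samples, replicate 8, lay above every control.

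With probes chosen on the even-numbered samples instead, the differences from CTR were 1.01 for aCD (exact p = 0.0253, adjusted p = 0.0455), 1.18 for INF (exact p = 0.00392, adjusted p = 0.0118), -0.224 for IBS (exact p = 0.376, adjusted p = 0.451) and 0.116 for iUC (exact p = 0.527, adjusted p = 0.527). For aUC the difference was smaller, at 2.98 ± 1.26 (SD, n = 7; exact p = 3.44e-05, adjusted p = 0.000206). Here 6 of 7 aUC samples lay above every control, and the lowest, at 0.838, lay within the control range. The aUC score exceeded that of aCD by 1.97 (exact p = 0.0303, adjusted p = 0.0455). With the suffix effect removed, the scores on the first choice were 1.30 in aCD (exact p = 0.00189, adjusted p = 0.00568) and 1.22 in INF (exact p = 0.0118, adjusted p = 0.0176). For aCD these values are consistent with the hypothesis of a shared part of the shift, at 1.11 against 3.52 in aUC. For INF, at 1.04, the scores did not follow the activity labels: 2 of the 3 samples labelled normal lay above every control, while the other, at 0.232, and the 1 labelled active, at 0.258, lay within the control range of -0.63 to 0.723. Values within array sets were not computed, since a set held at most 1 aCD sample and at most 2 INF samples. The aCD and INF samples spread widely, from 0.159 to 2.50 and from 0.232 to 2.05, so the group means describe samples that differ. For the 1 probe called in aCD against CTR chance cannot be excluded, since 14 of 100 splits gave at least as many (highest other 30). For the 4 probes of INF against CTR it is not firmly excluded either, with 3 of 100, not adjusted over the 8 comparisons, and 11 calls in another split. For aUC against iUC, 1 of 100 splits, the real one, gave 1707 calls and the highest other 1, which argues against chance, although this share is not adjusted either.

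iUC replicate 8 carries the label inactive and had an activity score within the range of the held-out aUC samples, 2.41 to 4.49. Without it, 2115 probes were called in aUC against iUC instead of 1707, and 37 instead of 41 in iUC against CTR.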
